A study of Mus musculus with 68 samples.

How the data were processed

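RNA was measured in neuronal nuclei of the nucleus accumbens, a ventral striatal region of the reward system, from male C57BL/6 mice. Per the labels' protocols, mice met an aggressive CD-1 male daily (chronic social defeat stress) and were then sorted by a social interaction test into stress-susceptible (SUS) and resilient (RES) animals. Non-stressed mice (NS) served as controls. Tissue punches from both hemispheres were taken 1 week or 3 weeks after the stress, samples were put in random order before processing, and nuclei stained for the neuronal protein NeuN were collected by flow sorting. Each mouse gave 2 libraries, which the labels call technical replicates. They were made with a modified Smart-seq3 reverse transcription followed by tagmentation, a method that joins cutting of cDNA and adapter addition in a single enzyme step.

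The deposited values are counts: whole numbers of reads per gene for 43432 genes in each of 68 libraries, with no normalization. The submitters' processing notes name Trim Galore, HISAT2, featureCounts and DESeq2, with no versions, and the mouse build mm10 (GRCm38). Per the file headers the counts come from featureCounts with exon intervals of each gene. Whether the counting used strand, and whether the molecular identifiers that Smart-seq3 can carry were used to remove duplicates, is not given in the sources used here. Counts are therefore treated as reads, and errors within a library cover counting only. Overlapping and antisense genes cannot be told apart without strand. Gene symbols were looked up by gene ID in reference tables, which held 97.96% of the 43432 IDs. Coordinates are those of the deposited files. Starts and ends were identical to GENCODE release M21 for 77.13% of the IDs.

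The counts of the 2 libraries of a mouse were summed, so that n is the number of mice (34 in 6 groups). Before summing, libraries were compared with each other. No library was identical to another, and the chi-square per degree of freedom between libraries of a mouse lay between 2.93 and 16 (median 7.03), against a median of 18.7 between libraries of different mice of a group. Genes were kept by filterByExpr (smallest count 10, smallest total count 15), which left 20310 genes and removed 23122. A joint model with 6 group means was fitted with edgeR 4.0.16 (TMM scaling, robust quasi-likelihood F test) in R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over the 20310 genes, with a threshold of 0.05, and all tests are two-sided. Log2 fold changes are given ± their standard error (SE), and expression as counts scaled to library size (CPM) with the SD between mice. The common biological coefficient of variation was 0.338. In all, 12 comparisons were made: the 3 phenotype comparisons in each week, the change from week 1 to week 3 within each phenotype, and the change of each phenotype difference between the weeks.

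The genes named were set by a rule. Among genes past the threshold with a mean of at least 2 CPM over all mice it takes the 12 with the largest and the 12 with the smallest log2 fold change (5 each outside the phenotype comparisons), and members of the lists that pass. Where fewer than 10 pass, it takes these and the genes with the lowest p up to 10 (5 outside the phenotype comparisons), and unnamed gene models are counted but not named. It adds 12 genes given whatever their p: Drd1, Drd2, Oprm1, Oprk1, Oprd1, Pdyn, Penk, Tac1, Fos, Fosb, Fkbp5 and Bdnf. The 35 gene lists cover cell types the punch or the sort could hold, striatal receptors and ion channels, opioid and stress systems, synapses, chromatin, the clock, energy metabolism, translation and stress responses. They were tested with camera (limma 3.58.1) on the edgeR counts with a preset correlation of 0.01 between genes, adjusted over the 210 tests of the 6 phenotype comparisons. The same test with the correlation estimated per list is given beside it. Groups, tests, lists, the naming rule and the settings to vary were fixed before the data were examined. The list tests of the other 6 comparisons, adjusted over another 210 tests, were added afterwards, as were 3 lists of neighbouring tissue (hypothalamic and preoptic neurons, septal, thalamic and bed nucleus neurons, meningeal fibroblasts).

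Marker levels per mouse are sums of CPM over a list, on a log2 scale, tested by exact two-sided permutation of mice. Correlations across mice have permutation p-values, whose smallest possible value is 1e-05. The agreement of fold changes used 100 permutations of the group labels, and 60 splits of the mice, the real one included, were counted for each comparison to see how often a grouping gave as much. The settings varied were DESeq2 1.42.0, RLE size factors, no filter, the mouse number as a block, each technical replicate alone, the groups of a comparison alone, limma voom with sample quality weights, and each mouse left out in turn. Settings added after the data were examined were marker scores of neighbouring tissue as covariates, surrogate variables (sva 3.50.0), 4 libraries with fewer than 19000 detected genes left out, and the genes Gm26917 and Gm42418 removed. These marker scores, also called region scores, were 2. The first pooled the hypothalamic and preoptic list with the septal, thalamic and bed nucleus list, and the second was that of glutamatergic projection neurons. Meningeal markers were not among them.

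The pipeline was tested on simulated counts with independent genes, drawn from the means and library sizes of these mice. For 3wSUS against 3wNS, 20310 genes were simulated. Of the changed genes at 10 CPM or more, 61.9% were recovered at a 2-fold change and 23.7% at a 1.5-fold change. For 3wSUS against 3wRES the shares were 79.5% and 47.1%, for 1wSUS against 1wNS 83.8% and 48.5%, and for the change of SUS versus NS between weeks 36.7% and 5.56%. Each comparison was simulated a single time, and 30 to 42 genes lie behind each of these shares. Differences in share between the comparisons of 2 groups are therefore not read as differences in power. In the real data the median SE at 10 CPM or more gave a 95% half-width of 0.331 to 0.35 on the log2 scale in the comparisons of 2 groups, and of 0.481 to 0.493 in the changes between weeks.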

Results

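The series holds 68 libraries of neuronal nuclei from the nucleus accumbens of 34 male mice, 2 technical replicate libraries per mouse. Week 1 after social defeat stress has 5 susceptible (1wSUS), 6 resilient (1wRES) and 6 non-stressed mice (1wNS), and week 3 has 6 susceptible (3wSUS), 6 resilient (3wRES) and 5 non-stressed mice (3wNS). The series title sets stress phenotypes beside opioid taking and gene expression. The comparisons ask which genes separate susceptible and resilient mice from controls and from each other, and whether this differs between the weeks. Libraries held 3.11 to 25.2 M counts (median 5.36), and summed mice 6.8 to 32.2 M. Mice of the groups had medians of 10.4 (1wSUS), 10.6 (1wRES), 14.3 (1wNS), 9.19 (3wSUS), 11.3 (3wRES) and 10.1 M (3wNS). Libraries detected 16438 to 23381 genes. The genes Gm26917 and Gm42418, which overlap ribosomal RNA sequence, took a median of 13% and 10.1% of the counts, and mitochondrially encoded genes 0.0498%.

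Neuronal identity genes of the striatum were abundant in every group. Penk, the enkephalin precursor of D2 medium spiny neurons (ENSMUSG00000045573, mm10 chromosome 4, 4133531 to 4138819, minus strand), stood at 870 CPM ± 393 (SD, n = 6) in 1wNS and 625 ± 358 (n = 5) in 3wNS. Drd1, the D1 dopamine receptor (ENSMUSG00000021478, chromosome 13, 54051186 to 54055658, minus strand), was at 108 ± 73.6 in 1wNS and 54.2 ± 53.3 in 3wNS, a range of 20.1 to 148 CPM within the latter group. Oprm1, the mu opioid receptor (ENSMUSG00000000766, chromosome 10, 6758506 to 7038198, plus strand), varied less, with 69.6 ± 19.9 in 1wNS and 66.3 ± 16.2 in 3wNS. The 2 libraries of a mouse correlated at a median Pearson r of 0.944 across genes (0.89 to 0.963). Libraries of different mice of a group correlated at 0.93, and 19 of 68 libraries were closest to the other library of their mouse. With genes of at least 10 CPM alone the values were 0.961, 0.925 and 40 of 68. At 10 CPM or more the median SD was 0.26 on the log2 scale between technical replicates and 0.22 between mice after the technical part was taken off.

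Of the 12 genes given whatever their p, none passed in any comparison. The kappa opioid receptor gene Oprk1 stood at 126 CPM ± 42.2 (SD, n = 6) in 1wNS, 135 ± 37.3 (n = 6) in 1wRES and 134 ± 39.8 (n = 5) in 1wSUS. At week 3 it stood at 88.6 ± 39.2 (n = 5) in 3wNS, 125 ± 36 (n = 6) in 3wRES and 116 ± 46.4 (n = 6) in 3wSUS. In the same order of groups, mean CPM was 54.5, 69.6, 67.9, 33.9, 57.5 and 52.9 for the dopamine receptor gene Drd2. It was 139, 158, 153, 98.3, 129 and 132 for Pdyn, the dynorphin precursor. Tac1, a substance P precursor of D1 neurons, had 152, 172, 189, 91.8, 136 and 132, and the delta opioid receptor gene Oprd1 12.5, 17.3, 12.5, 10, 11.7 and 12.6. The glucocorticoid target Fkbp5 had 15.7, 19.3, 19.4, 15, 15 and 16, and the growth factor Bdnf 4.03, 2.45, 2.7, 6.67, 4.26 and 5.99. Immediate early Fos had 10.1, 6.8, 3.35, 9.53, 3.07 and 6.09, and Fosb 1.37, 0.868, 0.732, 1.31, 0.652 and 1.73. At week 3 Drd1 differed from controls by a log2 fold change of 0.88 ± 0.54 in susceptible and 0.82 ± 0.54 in resilient mice, and Oprk1 by 0.52 ± 0.28 in resilient mice.

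**Figure D1:**
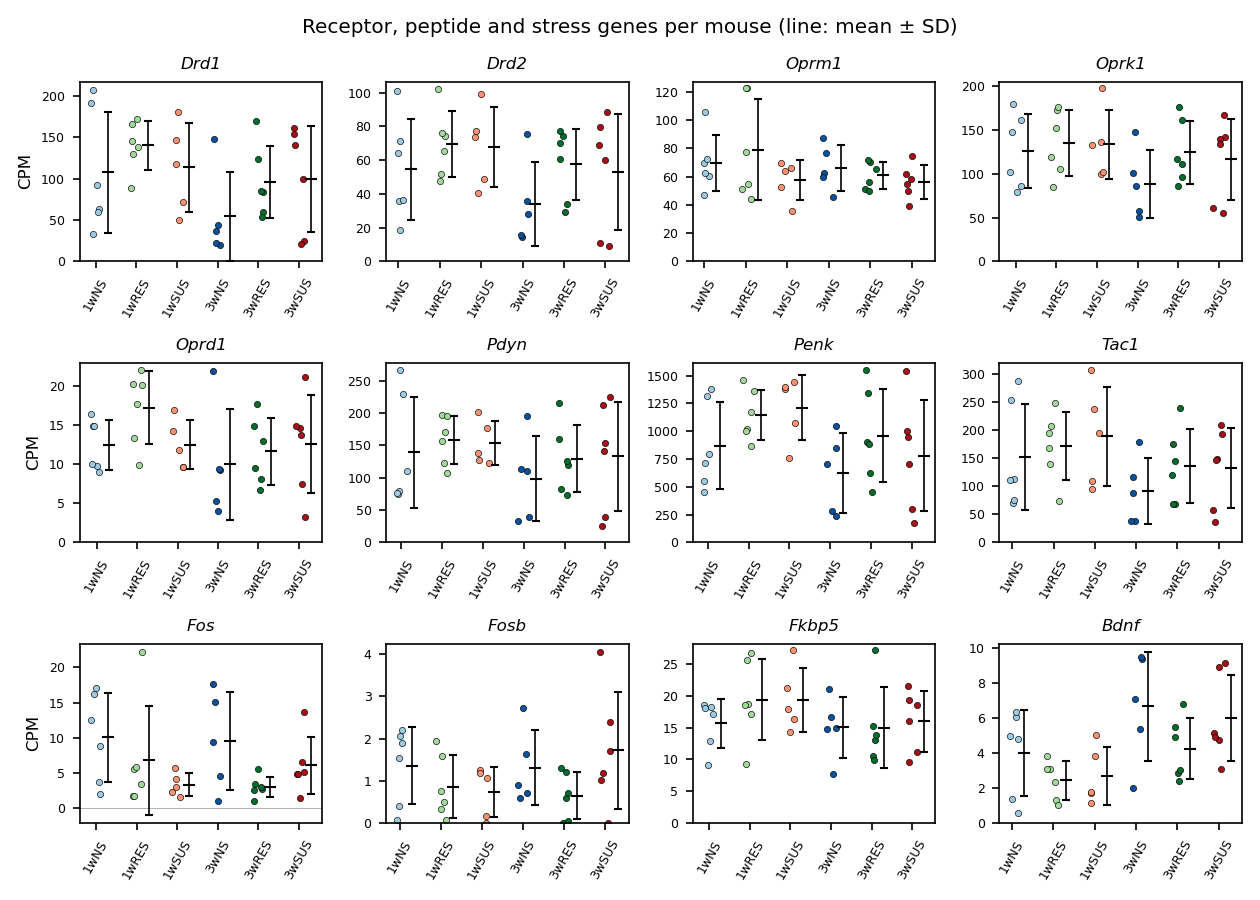
Expression in CPM (vertical axes) of 12 receptor, peptide and stress genes in each mouse, by group (horizontal axes); points are mice, lines the mean ± SD, with 5 or 6 mice per group. Groups overlap for each gene, as for Drd1, which ranges from 20.1 to 148 CPM in 3wNS and from 53.6 to 169 CPM in 3wRES.

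Susceptible mice against controls at week 1 showed lower values for the genes with the lowest p, none past the threshold. Cys1, which encodes a protein of primary cilia (ENSMUSG00000062563, chromosome 12, 24665838 to 24681813, minus strand), stood at 2.57 CPM ± 1.28 (SD, n = 5) in 1wSUS and 7.27 ± 3.61 (n = 6) in 1wNS, a log2 fold change of -1.56 ± 0.39. Kcnk9, a two-pore potassium channel (ENSMUSG00000036760, chromosome 15, 72512119 to 72546279, minus strand), was at 9.24 ± 3.36 against 21.2 ± 6.67 (-1.26 ± 0.37). All 5 1wSUS mice lay below all controls. Kcnk9 passed when adjusted over the list alone (inward rectifier and two-pore potassium channels, adjusted p = 0.0262), the only such member among the lists in this comparison. Nxt2 had -1.16 ± 0.32, Zpbp -1.02 ± 0.30, Fam198a -0.73 ± 0.21 and Zfp87 -0.70 ± 0.21. The oxidoreductase Ero1l (-0.54 ± 0.16), the elongation factor Eef1a2 (-0.50 ± 0.15), Fem1b (-0.42 ± 0.13) and the peptidase Xpnpep1 (-0.36 ± 0.10) complete the 10 with the lowest p. Fos, an immediate early gene induced by neuronal activity, had -1.66 ± 0.67, and its adjusted p in edgeR was 0.997, as for the other genes named here.

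Among the fixed lists, endothelial and mural markers were higher in 1wSUS than in 1wNS as a set (7 of 8 members, median log2 fold change 0.76, adjusted p = 0.00821). The pericyte gene Vtn stood at 1.65 ± 0.66 and Rgs5 at 1.06 ± 0.66. The p = 0.0028 of the list with an estimated correlation did not pass after adjustment (0.588). Immediate early genes were lower as a set (22 of 26 members, median -0.29, adjusted p = 0.0288, p = 0.322 with an estimated correlation), with Btg2 at -1.17 ± 0.46. Summed per mouse, these genes differed by -0.03 ± 0.21 (exact permutation p = 0.89). Peptide and receptor genes of the CRF and other stress peptide systems were lower (18 of 25, median -0.34, adjusted p = 0.044, p = 0.183 with an estimated correlation). Of these, the somatostatin receptor gene Sstr1 stood at -1.53 ± 0.64 and Crhr1 at 0.37 ± 0.17. Synaptic adhesion molecules were slightly lower (30 of 43, median -0.08, adjusted p = 0.0475, unadjusted p = 0.0251 with an estimated correlation, which was lost at 0.962 after adjustment), with Slitrk1 at -0.58 ± 0.21. Meningeal fibroblast markers stood beside the endothelial list at a log2 difference of 1.10 ± 0.43 between the same groups (exact permutation p = 0.0195). Adjusted over 27 tests of neighbouring tissue 0 passed, though with 462 or 924 arrangements of the mice a single complete separation could not have done so. Hypothalamic and preoptic markers, which move in the direction of the stress peptide list, stood at -0.82 ± 0.67 (exact permutation p = 0.247). Both lists hold the peptide gene Gal. Their common direction, and a loss of the stress peptide call with neighbouring tissue scores in a fit, may therefore be partly built in.

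By edgeR 0 of 20310 genes passed for 1wSUS against 1wNS. In all, 647 had an unadjusted p under 0.05 (277 higher, 370 lower) where chance alone gives 1016 (404 to 939 without 1 mouse), and DESeq2 and limma voom with quality weights also called 0. With surrogate variables in the fit, a setting added afterwards, Cys1 alone was called. The call for endothelial and mural markers, 1wSUS versus 1wNS, ended in 2 of 11 fits without a mouse (up to adjusted p = 0.0689 without 1wSUS mouse 5). The immediate early call ended in 5 of 11 such fits (up to 0.544 without 1wNS mouse 6), the stress peptide call in 6 (up to 0.257 without 1wNS mouse 1) and the adhesion call in 8 (up to 0.156 without 1wNS mouse 4). With the mouse number as a block the immediate early call ended (0.309). It held with marker scores of neighbouring tissue (4.14e-06) and with surrogate variables (3.6e-10) in the fit. The stress peptide call also ended with marker scores of neighbouring tissue (0.704) or surrogate variables (0.683) in the fit, and the adhesion call with surrogate variables (0.0811), while the fit without the libraries with the fewest genes ended the stress peptide call (0.0582). Replicate 2 libraries alone ended the endothelial (0.263), immediate early (0.155) and stress peptide (0.0981) calls, and replicate 1 alone the stress peptide (0.0854) and adhesion (0.455) calls.

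Resilient mice against controls at week 1 had still fewer genes at low p. Shisa2, which affects maturation of Wnt and FGF receptors (ENSMUSG00000044461, chromosome 14, 59625281 to 59631658, plus strand), stood at 1.21 CPM ± 0.537 (SD, n = 6) against 3.00 ± 1.09 (n = 6), a log2 fold change of -1.34 ± 0.38. Topors, a ubiquitin and SUMO ligase (chromosome 4, 40259601 to 40269850, minus strand), was at 12.1 ± 0.961 against 16.7 ± 1.8 (-0.52 ± 0.17). It was lower in 6 of 6 mice than in all controls. Values above 0 were found for the thyroid hormone transporter Slco1c1 (1.09 ± 0.36), the kinase Pkmyt1 (0.77 ± 0.27) and Nme5 (0.69 ± 0.24). They were below 0 for Ptpn14 (-1.31 ± 0.47), Rnf26 (-0.50 ± 0.18), Aph1c (-0.50 ± 0.18), Bbip1 (-0.44 ± 0.15) and Gpat4 (-0.29 ± 0.10). As sets, pan medium spiny neuron markers were higher in 1wRES (18 of 19, median 0.27, adjusted p = 0.0108, p = 0.316 with an estimated correlation). So were D2 medium spiny neuron markers (9 of 9, median 0.31, adjusted p = 0.044, p = 0.238 with an estimated correlation), with Penk at 0.36 ± 0.39 and Oprd1 at 0.41 ± 0.32. The stress peptide systems were lower (21 of 25, median -0.30, adjusted p = 0.025, p = 0.148 with an estimated correlation), with the oxytocin receptor gene Oxtr at -0.55 ± 0.34. Markers of hypothalamic and preoptic neurons stood at -0.48 ± 0.50 between the same groups (exact permutation p = 0.372).

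For 1wRES against 1wNS 0 genes passed by edgeR, with 299 at an unadjusted p under 0.05 (233 to 482 without 1 mouse). No list member passed when adjusted over the list alone, and DESeq2 and limma voom called 0. The call for pan medium spiny neuron markers, 1wRES versus 1wNS, ended in 3 of 12 fits without a mouse (up to adjusted p = 0.223 without 1wNS mouse 1). The D2 call ended in 8 of 12 such fits (up to 0.24 without 1wNS mouse 3) and the stress peptide call in 6 (up to 0.276 without 1wNS mouse 1). Marker scores of neighbouring tissue in the fit ended all 3 calls of this comparison (pan medium spiny 0.864, D2 0.717, stress peptides 0.282), and surrogate variables the pan medium spiny (0.104) and stress peptide (0.828) calls. Replicate 1 libraries alone ended the D2 (0.225) and stress peptide (0.0765) calls, replicate 2 alone the stress peptide call (0.0715), and the fit without a filter both (0.0613 and 0.0601).

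Susceptible against resilient mice at week 1, the direct contrast of the phenotypes, gave Ptgds, a prostaglandin D synthase (ENSMUSG00000015090, chromosome 2, 25466709 to 25470046, minus strand), at 45.2 CPM ± 29.6 (SD, n = 5) against 17.3 ± 11.9 (n = 6), a log2 fold change of 1.37 ± 0.38. Epha1, an ephrin receptor (chromosome 6, 42358487 to 42373268, minus strand), stood at 4.80 ± 1.2 against 2.02 ± 0.642 (1.24 ± 0.40). Zfp454 stood at 9.42 ± 0.915 against 5.53 ± 1.75 (0.77 ± 0.26). For both, 5 of 5 susceptible mice lay above all resilient ones. The cystine transporter Slc7a11 (1.20 ± 0.38), Rab3b (0.56 ± 0.18), the transcobalamin receptor Cd320 (0.40 ± 0.13) and the sodium pump subunit Atp1b3 (0.39 ± 0.13) were above 0. Zxdb (-1.31 ± 0.45), Cys1 (-1.19 ± 0.39) and Zfp87 (-0.66 ± 0.21) were below 0. Oprm1 was at 57.7 ± 14.1 CPM against 79 ± 35.8 (-0.43 ± 0.21). No gene passed by edgeR (0, with 391 at an unadjusted p under 0.05, 304 to 565 without 1 mouse). DESeq2 and limma voom called 0, and 0 of 35 lists passed the preset test. Per mouse, the summed endothelial and mural markers differed by 0.40 ± 0.10 (exact permutation p = 0.00866, adjusted 0.286), and meningeal markers by 1.13 ± 0.47 (exact permutation p = 0.039). Ptgds belongs to the meningeal list, which was chosen after the data were seen. It gave a mean of 45.2 of the 76.8 CPM summed in 1wSUS and 17.3 of 32.9 in 1wRES. The meningeal difference is therefore not separate from that of Ptgds.

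Susceptible mice against controls at week 3 gave the gene closest to the threshold in any phenotype comparison. Fam241b (ENSMUSG00000020083, chromosome 10, 62107655 to 62143920, minus strand) stood at 6.11 CPM ± 1.13 (SD, n = 6) in 3wSUS and 13.8 ± 3.62 (n = 5) in 3wNS. Its log2 fold change was -1.11 ± 0.20, with an adjusted p of 0.0675 in edgeR. DESeq2 called it as its only gene (-1.10, adjusted p = 0.00165), and limma voom with quality weights called it too (-1.15, adjusted p = 0.0204). EdgeR called it without 3wNS mouse 3 (-1.26, adjusted p = 0.00601), the control with the lowest value of this gene (7.65 CPM against 13.4 to 16.3), and not without any other mouse (adjusted p up to 0.579, without 3wNS mouse 5). 3wNS mouse 3 also had the lowest hypothalamic and preoptic sum of the controls (70.4 CPM against 295 to 646). Its medium spiny sum was the highest (8610 CPM against 2240 to 5460). Leaving it out therefore also widened the difference in these markers between the groups. The adjusted p of Fam241b was 0.999 with marker scores of neighbouring tissue in the fit, 0.998 with replicate 1 libraries alone, 0.978 with only the groups of the comparison and 0.957 without the libraries with the fewest genes. Sort1, the sorting receptor sortilin that binds the BDNF precursor (ENSMUSG00000068747, chromosome 3, 108284091 to 108361511, plus strand), was at 183 ± 50.9 against 124 ± 29.9 (0.61 ± 0.15, adjusted p = 0.948). Sort1 passed when adjusted over the list alone (BDNF and TrkB signalling, 0.00521). Klf10, a transcription factor induced by TGF-beta, was at 6.29 ± 3.96 against 2.10 ± 0.559 (1.60 ± 0.43). All 6 susceptible mice lay above all controls. Myo15b (2.21 ± 0.58), Fjx1 (1.11 ± 0.29), Mpped1 (0.90 ± 0.21), Atrnl1 (0.64 ± 0.17), Slc37a3 (0.41 ± 0.11) and R3hdm2 (0.41 ± 0.11) were above 0. The filamin-binding gene Fblim1 (-1.56 ± 0.36) was below 0.

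In the same comparison 9 lists passed the preset test. Markers of glutamatergic projection neurons, a cell type of cortex and other regions but not of the striatum, were higher in 3wSUS (10 of 12, median 1.37, adjusted p = 0.00417, unadjusted p = 0.0412 with an estimated correlation, which was lost at 0.962 after adjustment). Neurod2 stood at 3.31 ± 1.49, Slc30a3 at 2.79 ± 1.14 and Tbr1 at 1.13 ± 0.46. Pan medium spiny neuron markers were higher (17 of 19, median 0.54, adjusted p = 0.00417, p = 0.263 with an estimated correlation), with Rasd2 at 0.89 ± 0.48. With surrogate variables in the fit this list was called in the other direction (lower, adjusted p = 0.00999). Dopamine receptors and striatal cAMP signalling were higher too (23 of 32, median 0.30, adjusted p = 0.0475, p = 0.257 with an estimated correlation). Also higher were metabotropic glutamate receptors and scaffold (21 of 24, median 0.22, adjusted p = 0.00907, p = 0.153 with an estimated correlation). The same held for voltage-gated potassium and HCN channels (25 of 36, median 0.23, adjusted p = 0.035, unadjusted p = 0.0327 with an estimated correlation, which was lost at 0.962 after adjustment) and voltage-gated calcium and sodium channels (22 of 28, median 0.16, adjusted p = 0.0128, p = 0.0835 with an estimated correlation). Of their members, Grm8 at -0.74 ± 0.21, against the direction of its list, and Cacna2d1 at 0.54 ± 0.16 passed when adjusted over the list alone (0.0316 and 0.0491). Circadian clock genes were higher (19 of 23, median 0.17, adjusted p = 0.0194, p = 0.118 with an estimated correlation), with Per2 at 0.48 ± 0.19. Cytosolic ribosomal proteins were lower (47 of 69, median -0.10, adjusted p = 0.0338, p = 0.386 with an estimated correlation). Heat shock and unfolded protein response genes were lower too (24 of 29, median -0.15, adjusted p = 0.0128, p = 0.214 with an estimated correlation), with Pdia4 at -0.32 ± 0.16.

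Beside these lists, hypothalamic and preoptic markers differed by -1.65 ± 0.97 between 3wSUS and 3wNS (exact permutation p = 0.139). The susceptible group was split in these markers, which summed to 499 and 547 CPM in 3wSUS mice 4 and 5 and to 27.5 to 72.9 in the other 4 mice. Medium spiny markers summed to 2090 and 2050 CPM in mice 4 and 5 and to 8000 to 9410 in the others. Summed glutamatergic markers stood at 197 CPM ± 56.1 (SD, n = 6) against 113 ± 18.9 (n = 5). By edgeR 0 genes passed, with 886 at an unadjusted p under 0.05 (509 higher, 377 lower), while DESeq2 called 1 and limma voom with sample quality weights 209. The 886, below the 1016 of chance, became 1584 without 3wSUS mouse 4, 1922 without 3wSUS mouse 5 and 2057 without 3wNS mouse 3, and 582 to 791 without any other mouse. 3wNS mouse 3 had the lowest hypothalamic sum of the controls (70.4 CPM against 295 to 646). Leaving out any of these named mice therefore set the groups further apart in hypothalamic markers. With marker scores of neighbouring tissue in the fit 0 of these 9 lists kept their call, the glutamatergic list by construction, and with surrogate variables the glutamatergic list alone kept its call in the same direction (0.00999). Without single mice only the glutamatergic call held in each of 11 fits (highest adjusted p = 0.0178). The pan medium spiny call held in 8 of 11 such fits (up to 0.198 without 3wNS mouse 1), the dopamine call in 5 (0.347, same mouse) and the glutamate receptor call in 8 (0.0809, same mouse). The calcium and sodium channel call held in 8 (up to 0.102 without 3wNS mouse 4) and the clock call in 7 (0.105, same mouse). The potassium channel call held in 6 (up to 0.163 without 3wSUS mouse 3), the ribosomal call in 4 (0.319, 3wSUS mouse 2) and the heat shock call in 7 (0.143, 3wSUS mouse 6). Replicate 2 libraries alone ended the ribosomal (0.701), dopamine (0.228) and clock (0.0715) calls, replicate 1 alone the potassium channel call (0.0704). The dopamine call also ended without a filter (0.0611) and without the libraries with the fewest genes (0.0562).

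Resilient mice against controls at week 3 gave Zfp943, a zinc finger gene (ENSMUSG00000053347, chromosome 17, 21962552 to 22071168, plus strand), at 18.1 CPM ± 3.01 (SD, n = 6) against 12.3 ± 2.6 (n = 5), a log2 fold change of 0.59 ± 0.16. Cpox, an enzyme of heme synthesis (chromosome 16, 58670208 to 58680391, plus strand), was at 14.2 ± 2.86 against 21.1 ± 1.57 (-0.55 ± 0.16). The small GTPase gene Rhoq stood at 20.3 ± 2.1 against 14.9 ± 1.75 (0.48 ± 0.15). Neither overlapped between the groups. Sla (2.09 ± 0.66), the chemokine receptor Ackr2 (1.78 ± 0.53), the retinol carrier Rbp4 (1.37 ± 0.40), Arhgef3 (0.70 ± 0.22), Ercc6l2 (0.40 ± 0.12) and the corepressor Tle1 (0.38 ± 0.12) were above 0. The collagen gene Col6a3 (-1.96 ± 0.56) was below 0. Fos stood at 3.07 ± 1.45 CPM in 3wRES and 9.53 ± 6.96 in 3wNS (-1.58 ± 0.65).

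Pan medium spiny neuron markers were higher in 3wRES than in 3wNS (17 of 19, median 0.62, adjusted p = 6.72e-07, p = 0.0899 with an estimated correlation), with Gng7 at 0.82 ± 0.47 and Foxp1 at 0.71 ± 0.43. So were D1 markers (9 of 10, median 0.41, adjusted p = 0.011, p = 0.0528 with an estimated correlation) and D2 markers (8 of 9, median 0.31, adjusted p = 0.025, p = 0.201 with an estimated correlation). Dopamine receptors and striatal cAMP signalling were higher (24 of 32, median 0.24, adjusted p = 0.00417, p = 0.115 with an estimated correlation). Voltage-gated calcium and sodium channels (20 of 28, median 0.13, adjusted p = 0.025, p = 0.112 with an estimated correlation) and circadian clock genes (17 of 23, median 0.18, adjusted p = 0.0158, p = 0.11 with an estimated correlation) were higher as well, with the clock repressor Nr1d2 at 0.36 ± 0.12. Immediate early genes were lower (16 of 26, median -0.37, adjusted p = 0.0154, p = 0.279 with an estimated correlation). Btg2 stood at -1.22 ± 0.45, Npas4 at -0.95 ± 0.39 and Sik1 at -0.61 ± 0.23. Summed per mouse, immediate early genes differed by -0.19 ± 0.31 (exact permutation p = 0.528). Heat shock and unfolded protein response genes were lower (24 of 29, median -0.19, adjusted p = 0.00467, p = 0.162 with an estimated correlation). Bag3 stood at -1.84 ± 0.60 and Atf6 at 0.48 ± 0.21.

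Hypothalamic and preoptic markers differed by -1.16 ± 0.79 between 3wRES and 3wNS (exact permutation p = 0.182). With marker scores of neighbouring tissue in the fit the pan medium spiny (adjusted p = 0.0349) and immediate early calls (3.18e-11) held and the other 6 ended. With surrogate variables these and the dopamine call (0.0194) held and the other 5 ended. In 3wRES against 3wNS edgeR called 0 genes, with 701 at an unadjusted p under 0.05 (1958 without 3wNS mouse 3, and 397 to 1005 without any other mouse). 3wNS mouse 3 had the lowest hypothalamic and the highest medium spiny sum of these controls. No list member passed when adjusted over the list alone, and DESeq2 and limma voom called 0. The pan medium spiny and heat shock calls held without each mouse (highest adjusted p = 0.00129 and 0.0421), while replicate 2 libraries alone ended the heat shock (0.243), channel (0.056) and clock (0.0503) calls. The call for immediate early genes, 3wRES versus 3wNS, ended in 4 of 11 such fits (up to 0.51 without 3wNS mouse 3). The D1 (0.093), D2 (0.168), channel (0.133), clock (0.102) and dopamine (0.0581) calls ended without 3wNS mouse 4. The D1, dopamine and clock calls held in 9 of 11 such fits each, the channel call in 7 and the D2 call in 6.

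Susceptible against resilient mice at week 3 gave Ppm1l, a protein phosphatase (ENSMUSG00000027784, chromosome 3, 69316861 to 69560802, plus strand), at 71.9 CPM ± 20.2 (SD, n = 6) against 52.9 ± 4.86 (n = 6), a log2 fold change of 0.46 ± 0.14. Chrd, the BMP antagonist chordin, was at 43.6 ± 6.07 against 29.2 ± 5.83 (0.61 ± 0.20), and the actin-bundling gene Fscn1 at 29 ± 8.91 against 19.8 ± 4.29 (0.58 ± 0.18). Dock10, a guanine nucleotide exchange factor, stood at 116 ± 23.8 against 156 ± 28.6 (-0.40 ± 0.12) and Fam84b at -1.33 ± 0.40. Pkd2l2 (0.55 ± 0.18), Crtac1 (0.54 ± 0.18), Umps (0.49 ± 0.16), Dcun1d3 (0.48 ± 0.15) and Dcaf12 (0.42 ± 0.13) were above 0. Immediate early genes were higher in 3wSUS than in 3wRES as a set (24 of 26, median 0.48, adjusted p = 8.54e-06, p = 0.0813 with an estimated correlation). The activity-regulated Arc stood at 1.10 ± 0.54, Btg2 at 0.95 ± 0.44, Npas4 at 0.82 ± 0.38 and Dusp1 at 0.76 ± 0.34. Glutamatergic projection neuron markers were higher (12 of 12, median 0.63, adjusted p = 0.00417, unadjusted p = 0.0333 with an estimated correlation, which was lost at 0.962 after adjustment), with Slc30a3 at 1.39 ± 0.99. Mitochondrially encoded genes were lower (8 of 9, median -0.49, adjusted p = 0.00979, p = 0.116 with an estimated correlation), with mt-Nd1 at -0.89 ± 0.34 and mt-Cytb at -0.85 ± 0.35.

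EdgeR called 0 genes for 3wSUS against 3wRES, with 450 at an unadjusted p under 0.05 (419 to 633 without 1 mouse) and 0 calls from DESeq2 or limma voom, and no list member passed when adjusted over the list alone. The mitochondrial call ended without 3wRES mouse 3 (adjusted p = 0.421), while the immediate early (highest 0.0274) and glutamatergic calls (highest 0.0444) held without each of the 12 mice. With marker scores of neighbouring tissue in the fit the mitochondrial (0.32) and, by construction, the glutamatergic call (0.86) ended and the immediate early call (6.4e-05) held. The mitochondrial call also ended with surrogate variables (0.0647) and with replicate 1 libraries alone (0.117). The sum of immediate early genes per mouse differed by 0.25 ± 0.29 (exact permutation p = 0.418). In 4 of 6 susceptible mice it lay above all resilient mice (587 to 902 CPM against 348 to 537), while in 3wSUS mice 4 and 5 it lay below all of them (254 and 344). These 2 mice also had the highest hypothalamic and the lowest medium spiny sums of their group.

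**Figure D2:**
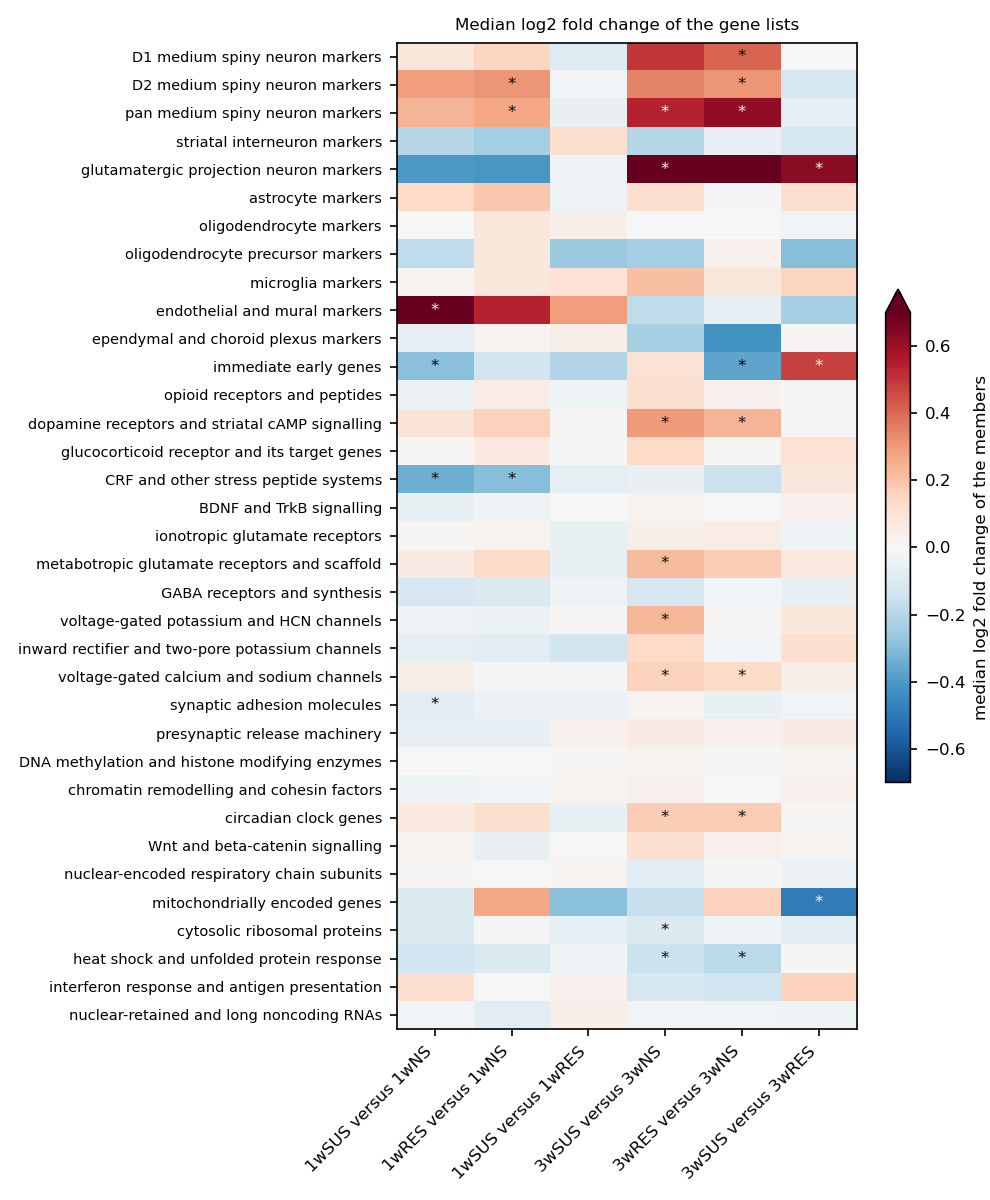
Median log2 fold change of the members (colour, saturated at the ends of the scale) of the 35 fixed lists (vertical axis) in the 6 phenotype comparisons (horizontal axis). Asterisks mark the 27 of 210 set tests past 0.05 with the preset correlation, such as immediate early genes in 3wSUS versus 3wRES (median 0.48); with an estimated correlation 0 passed.

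With the correlation between genes estimated per list, 0 of the 210 set tests passed after adjustment, the lowest adjusted p being 0.588. A further 19 lists had no call, and their lowest adjusted p over the 6 phenotype comparisons was as follows. Presynaptic release machinery reached 0.0515 in 3wSUS against 3wNS (21 of 30 higher, median 0.06), nuclear-encoded respiratory chain subunits 0.0779 in 3wSUS against 3wRES (38 of 54 lower, median -0.04) while GABA receptors and synthesis had 0.0839 in 1wSUS against 1wNS (17 of 22 lower, median -0.12). Inward rectifier and two-pore potassium channels reached 0.0921, striatal interneuron markers 0.105, ependymal and choroid plexus markers 0.134, Wnt and beta-catenin signalling 0.139, astrocyte markers 0.168 and interferon response and antigen presentation 0.301. Opioid receptors and peptides reached 0.506 (median -0.03 in 1wSUS against 1wRES), glucocorticoid receptor and its target genes 0.423, oligodendrocyte precursor markers 0.423, ionotropic glutamate receptors 0.506, microglia markers 0.506, chromatin remodelling and cohesin factors 0.506 and nuclear-retained and long noncoding RNAs 0.506. DNA methylation and histone modifying enzymes reached 0.54, oligodendrocyte markers 0.575, and BDNF and TrkB signalling 0.63.

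Between the weeks, Zic4, a zinc finger transcription factor (ENSMUSG00000036972, chromosome 9, 91362413 to 91389348, plus strand), stood at 20.4 CPM ± 23.6 (SD, n = 5) in 3wNS and 2.72 ± 1.13 (n = 6) in 1wNS, a log2 fold change of 2.87 ± 0.55. The protein kinase C gene Prkcd (chromosome 14, 30595356 to 30626210, minus strand) had 3.41 ± 0.72, the chloride channel gene Ano1 2.67 ± 0.61, Efna5 1.03 ± 0.24 and Spint2 0.78 ± 0.18. Between the same groups markers of septal, thalamic and bed nucleus neurons, Ano1 among them, stood at 0.86 ± 0.44 (exact permutation p = 0.0584) and hypothalamic and preoptic markers at 1.05 ± 0.72 (exact permutation p = 0.169). In susceptible mice Pex5l, a subunit that regulates HCN channels (chromosome 3, 32949408 to 33143247, minus strand), was at 61.5 ± 14.3 at week 3 and 39 ± 8.08 at week 1 (0.76 ± 0.16). It was followed by Ltbp1 (2.14 ± 0.50), Acss1 (1.35 ± 0.32), the nuclear receptor Rorb (1.25 ± 0.29) and Adamts2 (1.13 ± 0.26). In resilient mice Tshz3 had 1.12 ± 0.28, Pter 1.85 ± 0.51, the adrenergic receptor Adra2b -1.41 ± 0.38, Zmat5 -0.90 ± 0.25 and Man2b1 -0.59 ± 0.16. By edgeR 0 genes passed in each, with 952, 1228 and 870 at an unadjusted p under 0.05 for the control, susceptible and resilient mice (559 to 2003, 895 to 1735 and 635 to 1056 without 1 mouse). DESeq2 called 3 genes in controls (Zic4, Prkcd and Ano1), 8 in susceptible mice (Pex5l, Ltbp1, Nfia, Kcnk9, Adamts2, Kir3dl2, Rorb and Acss1) and 0 in resilient mice. Limma voom called 0, 1 (Pex5l) and 0. With only the groups of the comparison in the fit 3 genes were called in resilient mice, Adra2b among them. With surrogate variables genes were called in susceptible mice, Nfia among them. Without 3wNS mouse 4, which had 97.1 CPM of Prkcd against 7.21 to 15.5 in the other 3wNS mice, the lowest adjusted p in controls was 0.999 by edgeR, while without 3wNS mouse 3 edgeR called 4 genes (Zic4, Dlx1, Pip5k1b and Efna5). 3wNS mouse 3 had the lowest hypothalamic sum of its group (70.4 CPM against 295 to 646). Nfia, Kir3dl2, Dlx1 and Pip5k1b lie outside the naming rule and are named because these fits called them.

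The list tests between weeks called 9 lists in controls, 4 in susceptible and 4 in resilient mice, and 0 with an estimated correlation. Pan medium spiny neuron markers were lower at week 3 in controls (17 of 19, median -0.59, adjusted p = 4e-06, p = 0.107 with an estimated correlation), where hypothalamic and preoptic markers stood at 1.05 ± 0.72. They were also lower in susceptible mice (19 of 19, median -0.29, adjusted p = 0.00228, p = 0.247 with an estimated correlation) and in resilient mice (18 of 19, median -0.26, adjusted p = 0.042, p = 0.409 with an estimated correlation), where hypothalamic markers stood at 0.22 ± 0.94 (exact permutation p = 0.818) and 0.38 ± 0.60 (exact permutation p = 0.556). Clock genes were lower in controls (19 of 23, median -0.23, adjusted p = 0.000856, unadjusted p = 0.0364 with an estimated correlation, which was lost at 0.714 after adjustment). Nr1d2 (-0.42 ± 0.12), Per2 (-0.59 ± 0.19) and Rorb (0.96 ± 0.28) were the 3 that passed when adjusted over the list alone. Dopamine receptors and striatal cAMP signalling were lower in controls (25 of 32, median -0.39, adjusted p = 0.000312, p = 0.0624 with an estimated correlation). They were also lower in susceptible (26 of 32, adjusted p = 0.0283, p = 0.196 with an estimated correlation) and resilient mice (26 of 32, adjusted p = 0.042, p = 0.241 with an estimated correlation). Ribosomal protein genes were higher in controls (50 of 69, adjusted p = 0.0095, p = 0.29 with an estimated correlation) and resilient mice (50 of 69, adjusted p = 0.021, p = 0.325 with an estimated correlation). Further calls in controls were those of D1 (8 of 10 lower, adjusted p = 0.0365, p = 0.0889 with an estimated correlation), D2 (8 of 9 lower, adjusted p = 0.0248, p = 0.18 with an estimated correlation) and calcium and sodium channel (20 of 28 lower, adjusted p = 0.0403, p = 0.133 with an estimated correlation). The same held for mitochondrially encoded (9 of 9 higher, adjusted p = 0.0437, p = 0.202 with an estimated correlation) and interferon genes (15 of 19 higher, adjusted p = 0.0356, unadjusted p = 0.00722 with an estimated correlation, which was lost at 0.536 after adjustment). Immediate early genes were lower in resilient mice (22 of 26, median -0.39, adjusted p = 0.00177, p = 0.179 with an estimated correlation). Glutamatergic markers were higher in susceptible mice (11 of 12, median 1.08, adjusted p = 0.0243, p = 0.0813 with an estimated correlation). In susceptible mice inward rectifier and two-pore potassium channels were higher (12 of 16, median 0.26, adjusted p = 0.0229, unadjusted p = 0.00341 with an estimated correlation, which was lost at 0.536 after adjustment). Kcnk9 (1.48 ± 0.37) and Kcnj6 (1.11 ± 0.36) were among 13 list members that passed in susceptible mice when adjusted over the list alone, against 7 in controls and 1 in resilient mice. Week and collection day cannot be separated here, since each mouse was sampled at a single time.

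The changes of the phenotype differences between weeks were tested as such. In each of them an unnamed gene model had the lowest p of all. Among the genes that the naming rule allows, the 5 with the lowest p for SUS versus NS were R3hdm2 (0.64 ± 0.15), Tspan14 (1.53 ± 0.38), Dpp8 (0.52 ± 0.14), Xpnpep1 (0.54 ± 0.15) and Lingo1 (0.86 ± 0.23), a membrane protein that limits myelination. For RES versus NS they were Wdr34 (-0.48 ± 0.16), Bbip1 (0.67 ± 0.22), Zfp729b (1.05 ± 0.35), Zfp943 (0.66 ± 0.22) and Tshz3 (1.20 ± 0.41). For SUS versus RES they were Fscn1 (1.13 ± 0.26), Casp8ap2 (-0.84 ± 0.21), Pcdh1 (0.75 ± 0.22), Rab3b (-0.80 ± 0.25) and Ctbp1 (0.77 ± 0.24). By edgeR 0 genes passed in each. The lowest adjusted p, 0.963, was shared by Fscn1 and an unnamed gene model, both in SUS versus RES. At an unadjusted p under 0.05 there were 716, 319 and 445 genes (625 to 1092, 272 to 606 and 399 to 570 without 1 mouse), with 0 calls from DESeq2 or limma voom.

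Across genes, which are not independent replicates, the log2 fold changes of week 1 and week 3 correlated at Pearson r = 0.167 for SUS versus NS (permutation p = 0.297), 0.193 for RES versus NS (permutation p = 0.0792) and 0.00951 for SUS versus RES (permutation p = 0.921). Without 1 mouse these values ranged from 0.0714 to 0.237, from 0.0818 to 0.252 and from -0.0232 to 0.0502. Within a week, the fold changes of SUS and RES against their shared controls correlated at 0.543 in week 1 and 0.654 in week 3. Because the controls are shared, regrouped mice with no effect gave a mean of 0.462 (up to 0.665) and 0.521 (up to 0.819). The covariances were 0.067 against 0.0606 with no effect in week 1 (permutation p = 0.386) and 0.115 against 0.0859 in week 3 (permutation p = 0.149). With the controls split between the comparisons, the mean r was 0.00678 in week 1 and 0.152 in week 3.

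Cell type markers summed per mouse gave 0 of 66 differences past the threshold (lowest adjusted p = 0.286). With 462 or 924 arrangements of the mice in an exact test, a single complete separation of the groups could not pass after adjustment over 66 tests, so this 0 does not speak against a difference in cell types. Glutamatergic projection neuron markers differed by 0.78 ± 0.19 on the log2 scale between 3wSUS and 3wNS (exact permutation p = 0.00649), with 5 of 6 susceptible mice above all controls, and by 0.70 ± 0.29 between 3wSUS and 3wRES (exact permutation p = 0.039).

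Medium spiny neuron markers ranged 5.33-fold across mice, and hypothalamic and preoptic markers 24.9-fold, from 3wRES mouse 4 to 3wNS mouse 1. Across the 34 mice these scores were inversely related, with Pearson r = -0.882 and Spearman rho = -0.889 (permutation p = 1e-05 for each, the smallest the permutations can give). Adjusted over 8 relations the p-values were 4e-05 and 8e-05. Without the 2 mice farthest from the median r was -0.87, in week 1 it was -0.858, in week 3 -0.898, and within groups -0.909. Magel2, Prlr and Trh, abundant hypothalamic transcripts, ranged from 2.71 to 117, from 1.43 to 111 and from 3.56 to 108 CPM.

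**Figure D3:**
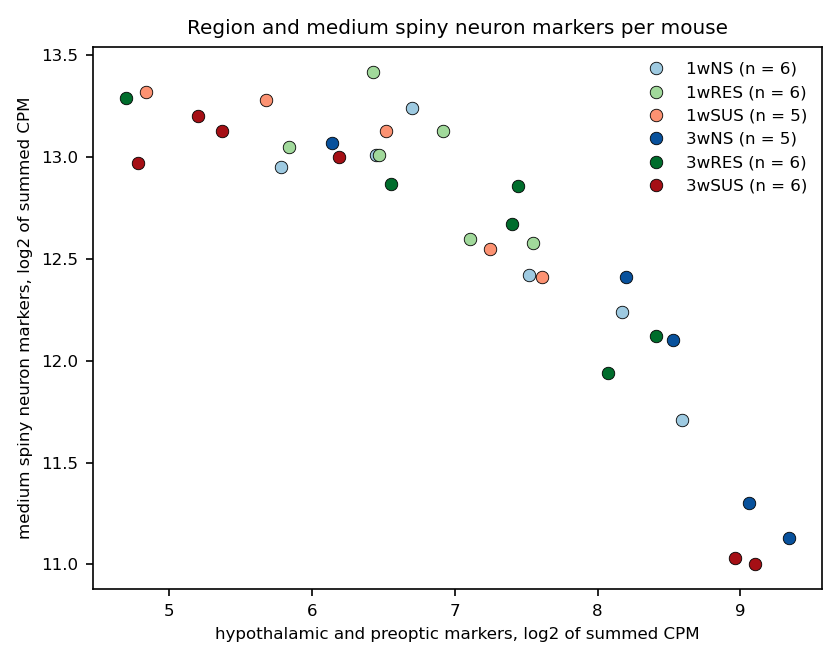
Log2 of the summed CPM of medium spiny neuron markers (vertical axis) against that of hypothalamic and preoptic markers (horizontal axis); each point is a mouse, coloured by group (n = 5 or 6). The scores are inversely related over all 34 mice (Pearson r = -0.882), and mice of every group spread along the relation.

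**Figure D4:**
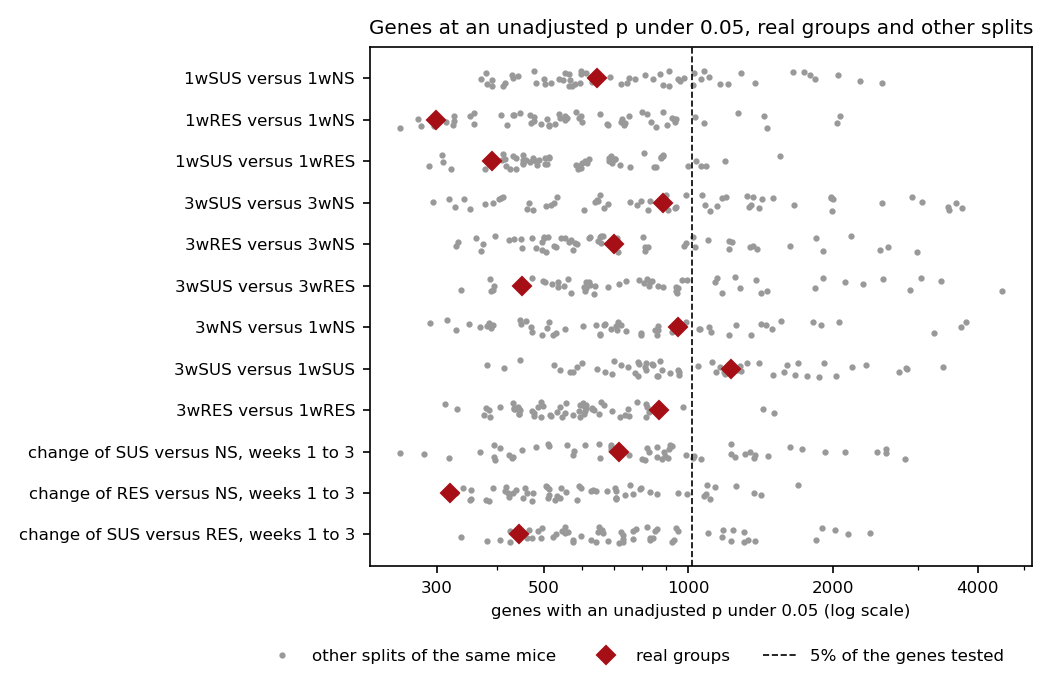
Genes at an unadjusted p under 0.05 (horizontal axis, log scale) in 12 comparisons (vertical axis). Each comparison has 60 splits of the same mice, the real groups among them. The dashed line is 5% of the genes tested, 1016. Real counts lie within the range of the other splits, except for the change of RES versus NS from week 1 to week 3. There the real 319 lies below all others (lowest 329). For 3wSUS versus 3wNS the real count was 886 (other splits up to 3717).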

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

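The tests of neighbouring tissue, of the share of Gm26917 and Gm42418 and of the variance between groups for the hypothalamic markers, and the list tests of changes between weeks, were chosen after the result was seen. Of 362 groups of mice tested, 9 held a mouse far from the others, where chance alone gives about 1 in 20. Striatal interneuron markers summed to 410 CPM in 3wRES mouse 2 (261 to 302 in the others), and microglia markers to 33.1 in 1wNS mouse 3 (42.6 to 45.9). Fam198a was at 10.4 CPM in 1wSUS mouse 2 (4.61 to 5.81), Fam241b at 7.65 in 3wNS mouse 3 (13.4 to 16.3), and Dcun1d3 at 10.3 in 3wRES mouse 2 (13.8 to 15.5). Umps was at 9.84 CPM in 3wSUS mouse 5 (16.6 to 19.7), and Prkcd at 97.1 in 3wNS mouse 4 (7.21 to 15.5). Man2b1 was at 58 CPM in 3wRES mouse 4 (36.4 to 42.8), and Dpp8 at 61.2 in 1wSUS mouse 2 (65.6 to 67.2).

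A difference between the weeks was found for 8 of 105 list tests with the preset correlation, and for 0 with an estimated correlation. For SUS versus NS the change from week 1 to week 3 was above 0 for glutamatergic projection neuron markers (11 of 12 above 0, median 1.25, adjusted p = 0.0095, p = 0.0607 with an estimated correlation) and immediate early genes (23 of 26, median 0.44, adjusted p = 0.0356, p = 0.315 with an estimated correlation). The medians of these lists went from -0.40 at week 1 to 1.37 at week 3 and from -0.29 to 0.10, the immediate early list being called as lower at week 1 and not called at week 3 (adjusted p = 0.52). The change was also above 0 for inward rectifier and two-pore potassium channels (13 of 16, median 0.39, adjusted p = 0.0393, unadjusted p = 0.00766 with an estimated correlation, which was lost at 0.536 after adjustment) and presynaptic release machinery (24 of 30, median 0.13, adjusted p = 0.0365, unadjusted p = 0.0251 with an estimated correlation, which was lost at 0.714 after adjustment). Nuclear-encoded respiratory chain subunits had the opposite sign (36 of 54 below 0, median -0.09, adjusted p = 0.042, p = 0.44 with an estimated correlation). Of the inward rectifier and two-pore potassium channels, Kcnk9 passed when adjusted over the list alone (0.028). No other list member did so for SUS versus NS. For RES versus NS the lists were pan medium spiny neuron markers (16 of 19 above 0, median 0.34, adjusted p = 0.042, p = 0.409 with an estimated correlation) and presynaptic release machinery (25 of 30, median 0.13, adjusted p = 0.0401, unadjusted p = 0.0278 with an estimated correlation, which was lost at 0.714 after adjustment). For SUS versus RES it was immediate early genes (24 of 26 above 0, median 0.67, adjusted p = 0.00023, p = 0.123 with an estimated correlation).

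Hypothalamic and medium spiny neuron markers moved against each other across the 34 mice (Pearson r = -0.882). Counts taken by Gm26917 and Gm42418 lower all other genes alike and so cannot by themselves give opposite movement, which is read from the pattern itself and not from a separate test. This reading replaced an earlier bound on the Spearman rho of the score with their share, which came to 0.468 (permutation p = 0.00545) and decided nothing. Library depth (Spearman rho = 0.232) is argued against too, and so are stress phenotype and week as the main cause, with 80.3% of the variance of the score between mice of the same group. Tissue outside the nucleus accumbens in the punch could account for it, though no record of punch placement was used here. The score was a property of the mouse (Pearson r = 0.973 between its replicate libraries), which argues against noise between libraries. It cannot tell tissue from other differences between mice, since the immediate early score also reached r = 0.93 between replicate libraries.

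Limma voom with sample quality weights called 209 genes between 3wSUS and 3wNS (99 higher, 110 lower), with weights from 0.339 for 3wSUS mouse 5 to 2.12 for 3wNS mouse 5. Of 60 splits of these mice, the real one included, 14 called as many (highest other 4662). In the 23 mice of the other groups 96.7% of the called genes followed the hypothalamic score in the direction of the difference, against 68.8% of all tested genes. With region scores in the fit 0 genes were called (lowest adjusted p = 0.587), as the median absolute log2 fold change of the 209 fell from 0.86 to 0.27. Tissue outside the nucleus accumbens and the grouping of these mice by chance both remain possible explanations, and an effect of the phenotype on top of them was not separated.

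Immediate early genes were higher in 3wSUS than in 3wRES as a set (median 0.48). With region and glutamatergic scores in the fit the median was 0.42 (quartiles 0.11 to 0.70), which argues against cortical glutamatergic neurons in the punch as the whole cause. With the preset correlation, removing a mouse ended the call for 0 of the 12 mice, which argues against 1 mouse as the whole cause. The adjusted p rose from 8.54e-06 to 0.0274 without 3wSUS mouse 3, which had the highest immediate early sum of its group (902 CPM). With an estimated correlation there was no call to lose. A p as low as the real 8.13e-08 came from 2 of 60 splits, the real one included (lowest other 2.46e-08), a share under the 5% set beforehand. The share is that of a list singled out among 210 tests, so it does not exclude sorting of the mice by chance. A difference in recent neuronal activity is a hypothesis only, since the list was singled out among 210 tests, its p was 0.0813 with an estimated correlation, and its sum per mouse gave an exact permutation p of 0.418, with 3wSUS mice 4 and 5 below all 3wRES mice.

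Splits of the same mice were counted, 60 per comparison with the real one included. As many genes at an unadjusted p under 0.05 as in the real groups came from 32 splits for 1wSUS versus 1wNS (real 647, highest other 2535), 56 for 1wRES versus 1wNS (299, 2070) and 55 for 1wSUS versus 1wRES (391, 1553). At week 3 it was 31 for SUS versus NS (886, 3717), 26 for RES versus NS (701, 2991) and 53 for SUS versus RES (450, 4495). Between weeks it was 20 in NS (952, 3786), 21 in SUS (1228, 3391) and 4 in RES (870, 1506), and for the changes 36 for SUS versus NS (716, 2825), 60 for RES versus NS (319, 1694) and 55 for SUS versus RES (445, 2394). Unadjusted counts were compared because the adjusted counts were 0. For called lists, adjusted within each comparison, as many came from 57 splits for 1wSUS versus 1wNS (real 1, highest other 12) and 54 for 1wRES versus 1wNS (2, 14). For 1wSUS versus 1wRES the real count was 0 (highest other 12), so that all 60 splits reach it whatever the data and this count decides nothing. At week 3 it was 15 for SUS versus NS (11, 16), 23 for RES versus NS (8, 16) and 52 for SUS versus RES (3, 15). Some splits gave several times the real count of genes, which points to a structure of the samples. Sorting of the mice by chance could not be excluded for any of the counts given here.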

How the results depend on the processing

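Region scores, surrogate variables, the libraries with the fewest genes and the removal of Gm26917 and Gm42418 were tests chosen after the result was seen. Gene counts were 0 in all 12 comparisons with edgeR and stayed 0 with RLE size factors, no filter, either replicate alone, region scores, without the libraries with the fewest genes, and without Gm26917 and Gm42418. DESeq2 called 1 gene in 3wSUS versus 3wNS, 3 in 3wNS versus 1wNS and 8 in 3wSUS versus 1wSUS; limma voom with quality weights called 209 in 3wSUS versus 3wNS and 1 in 3wSUS versus 1wSUS. With only the groups of the comparison 3 were called in 3wRES versus 1wRES (Adra2b, Clic6 and Sema5b), and with surrogate variables 1 in 1wSUS versus 1wNS (Cys1) and 4 in 3wSUS versus 1wSUS (Ubap1l, Mpped1, Nfia and Il31ra). Without 1 mouse the counts ranged from 0 to 1 in 3wSUS versus 3wNS and from 0 to 4 in 3wNS versus 1wNS (Zic4, Dlx1, Pip5k1b and Efna5), and stayed at 0 elsewhere. Genes outside the naming rule were named after their values were seen. Called lists numbered 27, between 19 and 31 under other settings, 0 with an estimated correlation and 12 to 36 without 1 mouse. Of 269 values of the called lists under other settings 177 kept their call, 91 lost it and 1 reversed: pan medium spiny neuron markers in 3wSUS versus 3wNS were lower with surrogate variables (adjusted p = 0.00999), and the cause was not tested. The endothelial list could not be tested with replicate 1 libraries, which left too few members. Mouse numbers as a block gave 0 genes and 29 lists, and ended 5 list calls. Mice of different groups with the same number had a median r of -0.0156 (81 pairs), others 0.00114 (400 pairs), and 4 of 34 mice were closest to a mouse of their number, so the numbers were not taken as pairs. The technical replicate r was 0.965 with all genes of at least 1 count (0.944 otherwise), with 15 of 68 libraries closest to their own mouse (19 otherwise). Without 1 mouse the agreement between weeks ranged from 0.0714 to 0.237 (SUS versus NS), 0.0818 to 0.252 (RES versus NS) and -0.0232 to 0.0502 (SUS versus RES), and within weeks from 0.477 to 0.624 and 0.56 to 0.765. Marker levels past the threshold stayed at 0, which shows no stability, since with 462 or 924 arrangements of the mice, or fewer without a mouse, no single difference could pass over 66 tests. Of 1943 values of named genes 89 had the other sign. In counts simulated a single time for 1wSUS versus 1wNS, 2-fold changes were recovered in 83.8% of 37 changed genes at 10 CPM or more. At any level they were recovered in 46.3% of 67 changed genes.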

Other observations

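The relations of immediate early, meningeal and endothelial scores were tests chosen after the data were seen. Immediate early gene sums followed medium spiny neuron markers across the 34 mice, with Pearson r = 0.747 (permutation p = 1e-05, the smallest the permutations can give) and Spearman rho = 0.656 (permutation p = 3e-05). Without the 2 mice farthest from the median r was 0.683, in week 1 it was 0.5, in week 3 0.832, and adjusted over 8 relations the p-values were 4e-05 and 0.00012. They ran against hypothalamic markers (Pearson r = -0.633, permutation p = 8e-05; Spearman rho = -0.639, permutation p = 1e-04; without the 2 farthest -0.623, in week 1 -0.332, in week 3 -0.765; adjusted over 8 relations 0.000213 and 0.000267).

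Meningeal fibroblast and endothelial markers moved together across mice, with Pearson r = 0.517 (permutation p = 0.00197) and Spearman rho = 0.416 (permutation p = 0.0149). Without the 2 farthest mice r was 0.311, in week 1 it was 0.783, in week 3 0.123, and adjusted over 8 relations the p-values were 0.00394 and 0.0238. Between the 2 libraries of a mouse the endothelial score correlated only at Pearson r = 0.482, and the meningeal score at 0.846. Ptgds, a meningeal transcript, ranged from 9.01 to 93.5 CPM and was highest in 1wSUS mouse 1. Ano1 (1.27 to 71.9 CPM) and Trpc4 (8.09 to 90.2 CPM), markers of septal and thalamic neurons, were highest in 3wNS mouse 4. The first principal component held 19.4% of the variance between mice and correlated with the hypothalamic score at r = 0.966 and with the medium spiny neuron score at -0.966, and the third (4.93%) with the glutamatergic score at 0.786. The first component also correlated with the share of Gm26917 and Gm42418 at r = 0.599. Among the genes with the strongest weights on it, Slc17a6 of the glutamatergic list lay with the hypothalamic score. Slc17a7, Neurod2 and Slc30a3 of the same list lay against that score.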
